A study of Rattus norvegicus with 16 samples.

How the data were processed

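RNA of 8 peritoneal mesotheliomas of F344 rats was measured on 2-colour Agilent rat oligonucleotide arrays, 4 tumours of rats exposed for 2 years to bromochloroacetic acid (BCA) and 4 of rats exposed for 2 years to o-nitrotoluene (o-NT). Every array set a tumour against Fred-PE, a non-transformed rat mesothelial cell line at passage 8. Each tumour was hybridized on 2 arrays with the dyes exchanged, which gave 16 arrays. Per the labels' protocols, 500 ng of total RNA was amplified, 750 ng of labelled cRNA per dye was hybridized for 17 hours, and Agilent Feature Extraction 7.5 was run with its default settings. The file headers record version A.7.5.1.

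The deposited scanner files hold the mean signal intensity of each channel, the median background intensity, spot flags and a log10 ratio. Per the file headers, the log10 ratio was made after spatial detrending and a LOWESS dye normalization, with local background subtraction turned off. The deposited series table also holds log10 ratios, written as tumour over Fred-PE on every array. These followed the scanner files' ratios with correlations of 0.982 to 0.999 across probes.

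The ratios analysed here were computed from the intensities with limma 3.58.1 in R 4.3.3. Background was corrected by normexp with an offset of 50, and each array was normalized by loess with control spots given no weight. The sign was turned on arrays with the tumour in Cy3, so that all log2 ratios are tumour over Fred-PE. Spots flagged as non-uniform or population outliers were left out. The 2 arrays of a tumour were averaged, so that each tumour counted as 1 replicate. A probe was kept if it was well above background in either channel on at least 8 of the 16 arrays, and tested if at least 3 of 4 tumours of each chemical had a value. Of 20500 gene probes, 19737 passed the first filter and 19628 were tested.

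Genes were named by matching each probe's accession to the rat RefSeq table supplied with the data, or by the symbol in the file's own description. This named 3725 of the tested probes and left 15903 unnamed. The named probes stood for 3623 genes. Where a gene had several tested probes, the probe with the highest mean intensity was used. Of 102 such genes, none had probes called in opposite directions and 19 had only some probes called.

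A linear model with a mean for each chemical was fitted over all 8 tumours, with limma's empirical Bayes moderated test, two-sided. Calls were made at a Benjamini-Hochberg adjusted p under 0.05 over all tested probes. The comparisons were all tumours, the BCA tumours and the o-NT tumours against the reference, BCA against o-NT tumours, o-NT tumours at 2000 against 1250 ppm, and a slope of the BCA tumours over log2 dose. Gene lists, 28 in number and written before the data were examined, were tested by camera with an inter-gene correlation of 0.01. Camera with an estimated correlation and fry were run beside it. Lists needed at least 5 measured genes, and the list of red blood cell markers, with 4, was not tested. Camera used the genes with a value in all 8 tumours. Some named genes lacked a value in 1 tumour, and Ccng1 in 2, and their means use the tumours present.

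The genes named follow a rule fixed before the data were examined. For the tumours against the reference it takes the 10 largest rises and the 10 largest falls among called genes with the same sign in all 8 tumours. It adds up to 4 called members per gene list with the largest change, and 20 genes fixed by name, of which 12 were measured. For BCA against o-NT it takes the 10 genes with the smallest p, since none passed. A few genes that the rule takes are not reported here. Where the channel of a group was saturated on every array, the change is given as a bound beside the measured mean.

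The alternatives tried were other background corrections and normalizations, the deposited ratios, other filters, each dye orientation alone, all 16 arrays with a dye term and the tumour as a random block, an intensity trend with robust estimation, the day of image extraction as a block, and leaving out each tumour in turn. One was chosen after the data were seen: the mean of the skeletal muscle list as a covariate. In the fits with a random block, the day as a fixed block or an intensity trend, lists were tested by camera's preranked form on the moderated t values. There the list test changed together with the fit. Arrays were extracted on 4 days, 1 slide per array. Day 1 held o-NT 1 and 2, day 2 held BCA 3 and 4 with o-NT 3 and 4, and day 3 held BCA 1 and 2, except that 1 array of BCA 2 was extracted on day 4. The day was taken per tumour, with BCA 2 on day 3.

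The steps were tested on simulated data. With 200 of 19628 probes changed, the test of all tumours against the reference recovered 86.6% of changes of 0.5 log2 units and 97.0% of changes of 1. For BCA tumours against the reference these were 83.6% and 91.0%, and for o-NT tumours 70.1% and 91.0%. Both chemicals were simulated with the same spread, so the gap between them comes from the random draws. A difference in spread between the chemicals was not simulated. The test of BCA against o-NT recovered 50.7% of changes of 0.5, 86.6% of changes of 1 and 92.4% of changes of 2. The test of o-NT dose recovered 19.4% of changes of 0.5 and 73.1% of changes of 1. The BCA dose slope recovered 70.1% of slopes of 0.5 and 83.6% of slopes of 1. False calls numbered 7 to 17 per comparison. Gene lists moved on purpose were called (2 of 2 and 1 of 1), with no other list called. The simulated genes were drawn independently, over a reference without variation. The false calls therefore do not cover correlated genes or a reference that varies. When the tumour channel of bright probes was multiplied by known factors on the real arrays, the log2 ratios moved in the right direction at all 200 probes, by medians of 0.966 to 0.974 of the change made.

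On each array 90.9% to 97.4% of gene probes were well above background in the tumour channel and 90.8% to 96.7% in the reference channel. Between 8 and 25 gene probes per array were saturated and 4 to 237 carried an outlier flag. The number of tumours limits the precision of every comparison. Fred-PE was a single RNA without replicates of its own, so the tests against the reference leave out its variation.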

Results

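Expression was measured in 8 rat peritoneal mesotheliomas, each against the mesothelial line Fred-PE on a pair of dye-exchanged arrays. The BCA group had 2 tumours at 250 mg/l, 1 at 500 mg/l and 1 at 1000 mg/l. The o-NT group had 2 tumours at 1250 ppm and 2 at 2000 ppm. Median signals of the gene probes were 412 to 600 in the tumour channel and 423 to 558 in the reference channel, over background medians of 274 to 297. The log2 ratios of a tumour's 2 arrays correlated across probes at 0.873 to 0.937. Tumours correlated with each other at 0.867 to 0.944 within the BCA group, at 0.622 to 0.890 within the o-NT group, and at 0.652 to 0.932 between groups. Tumour o-NT 1 had the lowest mean correlation with the others, 0.714. Genes are not independent replicates, so these correlations describe the arrays only.

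The first comparison asks what sets the mesotheliomas apart from non-transformed mesothelial cells. The mesothelial marker mesothelin (Msln) was raised by 4.57 ± 0.12 log2 units (SE, n = 8 tumours), and podocalyxin (Podxl), another mesothelial surface protein, by 4.74. The largest rise was in the ubiquitin-like modifier Ubd, at 5.83 ± 0.10, followed by the tetraspanin Tspan8 at 5.24. Falls were led by the CCN family of matricellular genes, with Ccn2 at -6.20 ± 0.07, Ccn3 at -5.47 ± 0.27 and Ccn1 at -5.47 ± 0.07. All of these had the same sign in all 8 tumours. The reference signal was saturated for Ccn2 on 7 and for Spp1 on 15 of 16 arrays, so their falls are underestimates.

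The other large rises were in the homeobox gene Rhox5 (4.50), the chemokine receptor Ackr3 (4.49), the interferon-induced GTPase Gbp2 (4.47), the macrophage lectin Clec10a (4.27), the complement protease C1s (4.27) and lysozyme Lyz2 (4.15). The other large falls were in the interleukin-33 receptor Il1rl1 (-5.36), Cyp1b1 (-4.83), osteopontin (Spp1, -4.82), nonmuscle myosin Myh10 (-4.50), the cadherin Fat1 (-4.43), Ltbp2 (-4.28) and Ddah1 (-3.95). These 20 genes had adjusted p from 5.72e-10 to 1.70e-05, and each was higher, or each lower, in 8 of 8 tumours. In all, 9442 of 19628 probes were called, 4729 higher and 4713 lower. Of these, 1503 differed by at least 2-fold, 783 higher and 720 lower. Fred-PE was 1 RNA, and in 20 simulations of unchanged tumours over a reference that varies like 1 tumour, the same test called on average 3430 probes higher and 3418 lower, 81.9 and 82.0 of them by at least 2-fold. Among named genes, 979 were called higher and 865 lower out of 3623.

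**Figure D1:**
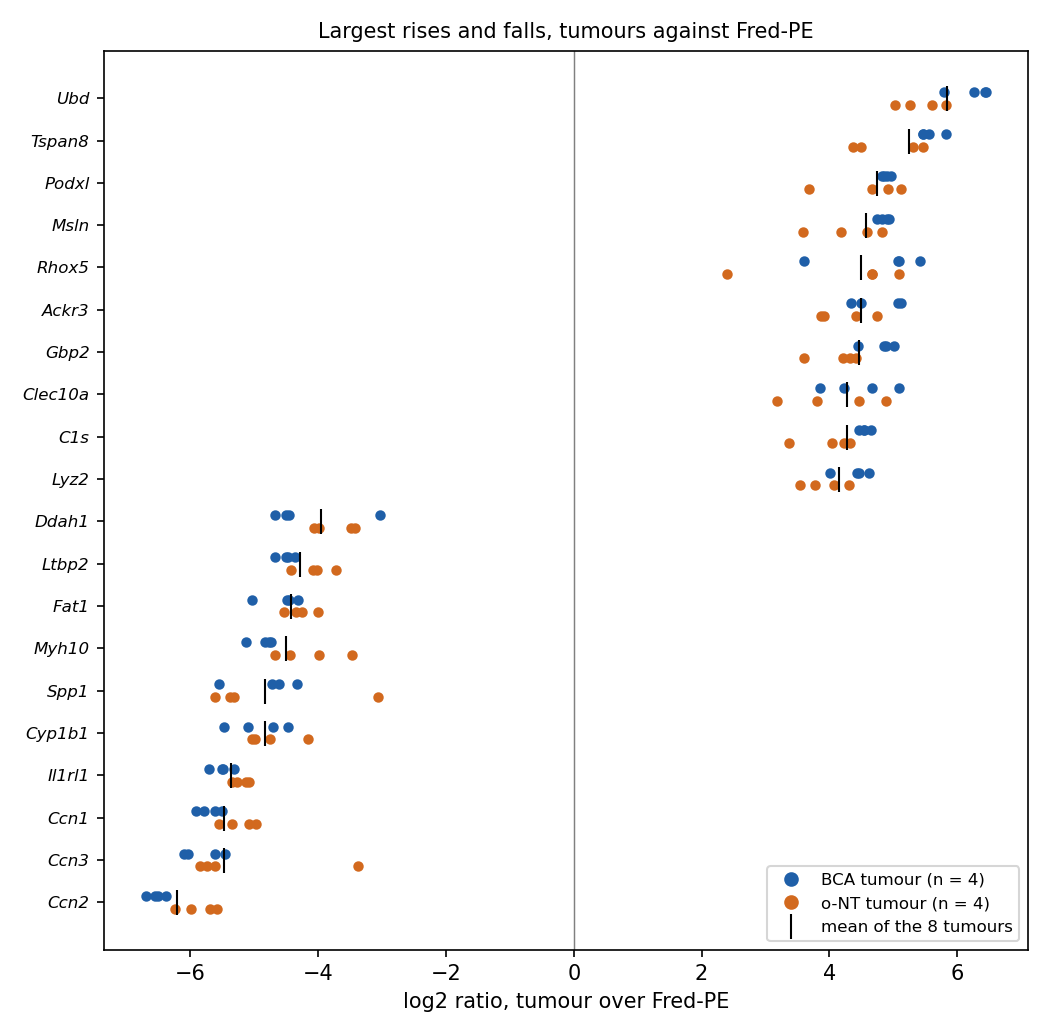
Log2 ratio over Fred-PE of the genes with the largest rises and falls, per tumour (BCA blue, o-NT orange, 4 each; bars mark the mean of the 8 tumours). Every tumour lies on the same side of 0 for all 20 genes, and o-NT 1 and o-NT 2 stand apart for Rhox5, Ccn3 and Spp1.

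Genes of the immune response rose in the tumours as groups. All 8 measured genes of MHC class II and antigen presentation were called higher, with a list median of 2.33 log2 units (camera adjusted p 6.29e-05, adjusted p = 0.289 with an estimated correlation), among them the immunoproteasome subunits Psmb9 (4.04) and Psmb8 (3.37), B2m (2.43) and Cd74 (2.36). Below, the list is shortened to MHC class II, though it also holds antigen presentation genes outside that class, such as Psmb9, Psmb8 and B2m. Interferon response genes had a median of 2.0 with 7 of 8 called higher (adjusted p 0.000698, adjusted p = 0.295 with an estimated correlation), including Psme2 (2.67), Oas1a (2.55) and Psme1 (2.38) beside Gbp2. Macrophage and myeloid markers had a median of 2.01 with 10 of 12 called higher (adjusted p 0.000698, adjusted p = 0.289 with an estimated correlation), including Fcgr2a (3.34) and Coro1a (3.27) beside Clec10a and Lyz2. Complement and acute phase genes had 9 of 13 called higher and none lower (adjusted p 0.00245, adjusted p = 0.289 with an estimated correlation). Of these C3 rose by 3.17 and A2m by 3.06, beside C1s.

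Lymphocyte markers rose less, with a median of 0.52 and 7 of 14 called higher (adjusted p 0.0350, adjusted p = 0.421 with an estimated correlation), including Cd5 (1.69), Nkg7 (0.85), Il2rb (0.71) and Cd2 (0.60). Without BCA 4 the median fell to 0.28 and Il2rb to 0.45, and the list lost its call without o-NT 1 or o-NT 2 (adjusted p 0.0679 and 0.0588). It also lost it with the tumour or the day as a random block (adjusted p 0.257 and 0.313), where the list test changed too, among 9 alternatives in all. Il2rb lost its call without o-NT 1, 2, 3 or 4 in turn, and Nkg7 without o-NT 2, 3 or 4. Cytokines and chemokines went both ways, 10 of 25 higher and 6 lower (median 0.07, adjusted p 0.478), with Il10 (2.77), Cxcl10 (2.77), Ccl5 (2.30) and Cx3cl1 (2.28) among the higher.

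Mesothelial markers were higher as a list, with a median of 1.6 (adjusted p 0.0161, adjusted p = 0.379 with an estimated correlation) and 4 of 6 genes called higher, including Slpi (2.22) and Wt1 (0.98) beside Podxl and Msln. Skeletal muscle markers were also higher, with a median of 2.04 and 6 of 8 genes called (adjusted p 0.0335, adjusted p = 0.646 with an estimated correlation), among them Myl11 (3.14), Actn3 (2.85), Ckm (2.53) and Mb (2.36). The muscle list differed widely between tumours, from 3.88 in o-NT 1 and 3.35 in o-NT 4 to 0.18 in BCA 4 and 0.07 in o-NT 2, and without o-NT 1 it was not called (adjusted p 0.0679). Nor was it called with the tumour or the day as a random block (adjusted p 0.257 and 0.313) or with an intensity trend (adjusted p 0.324). These fits also changed the list test, so the lost calls cannot be credited to the block or the trend alone. Adipocyte markers included Lpl (3.26), Cd36 (2.68), Fabp4 (1.88) and Scd2 (0.94), with 6 of 14 called higher and none lower, yet the list did not pass (median 0.08, adjusted p 0.0594). It passed without BCA 1 or BCA 3 (adjusted p 0.0367 and 0.0443), and Scd2 lost its call without any 1 of 6 tumours, all except BCA 1 and o-NT 1.

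Matrix, adhesion and sterol genes fell. Collagens and matrix genes had a median of -1.40 with 9 of 11 called lower (adjusted p 0.000304, adjusted p = 0.306 with an estimated correlation), including Fbln5 (-2.44), Col5a1 (-2.32) and Col1a2 (-2.43) beside Spp1. The reference signal of Col1a2 was saturated on all 16 arrays, so Col1a2 was at least 5.38-fold lower. Genes of the mesenchymal transition had a median of -0.66 with 10 of 13 lower and 1 higher (adjusted p 0.000633, adjusted p = 0.289 with an estimated correlation), including Tgfb3 (-2.88) and Tgfb2 (-1.77) beside Ccn2 and Ccn1. Integrins and focal adhesion genes had a median of -0.92 with 7 of 8 lower and 1 higher (adjusted p 0.00245, adjusted p = 0.295 with an estimated correlation), including Actn4 (-2.53), Itgb1 (-2.05), Itgb5 (-1.35) and Ilk (-1.20). Cholesterol synthesis genes had a median of -1.05 with 10 of 13 lower (adjusted p 6.29e-05, adjusted p = 0.306 with an estimated correlation), including Msmo1 (-2.06), Cyp51 (-1.88), Fdps (-1.73) and Sqle (-1.39).

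In all, camera called 11 lists, the 7 higher and 4 lower ones described above. With an estimated inter-gene correlation none of the 27 tested lists passed (lowest adjusted p 0.289). By fry, which asks whether a list's genes move 1 way on balance, 22 passed. When p-values were adjusted over the list alone, the muscle list had 7 genes called higher and the lymphocyte list 8, and the other called lists had the same counts.

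The remaining 16 lists were not called. Smooth muscle and pericyte markers had 4 of 7 called lower and 2 higher (median -1.48, adjusted p 0.579), with Cnn1 (-3.80) and Cspg4 (-3.69) lower and Des higher (1.96). The median is the value of Actg2, whose other probe was at -3.86. Tagln fell by 3.70, and its reference signal was saturated on every array, so Tagln was at least 13.0-fold lower. Matrix proteases and inhibitors went both ways (median -0.04, adjusted p 0.579), with Adamts1 (-3.27), Mmp23 (-2.59) and Mmp16 (-2.47) lower. Growth factors and receptors had 10 of 23 lower and 6 higher (median -0.08, adjusted p 0.0586), with Vegfc (-3.16), Nrg1 (-2.32) and Bdnf (-1.89) lower and Ptn (2.10) higher. This list passed without o-NT 2 (adjusted p 0.0452), with the tumour or the day as a random block (0.0357 and 0.0322), with an intensity trend (0.0145) and with a normexp offset of 0 (0.0483). The matrix protease list passed with the tumour as a random block (adjusted p 0.0399). The block and trend fits also changed the list test.

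In the IGF axis, Igfbp2 (3.15), Igfbp3 (2.46) and Igf2 (1.5) rose and Igf2r fell (-1.38), with a list median of 0.00 (adjusted p 0.780). In Wnt signalling, Wnt4 rose (3.48) and the receptors Fzd1 (-2.83) and Fzd2 (-1.13) fell, while Axin1 rose by 0.41 (median -0.03, adjusted p 0.579). Stress MAPK genes had 3 of 12 called higher and 4 lower, with a list median of 0.03 (adjusted p 0.688). The lower ones were Dusp1 (-2.10), Junb (-1.51), Gadd45a (-0.91) and Ddit3 (-0.75). Among p53 targets and DNA damage genes, 5 of 20 were called higher and 9 lower (median -0.03, adjusted p 0.478), with Btg2 (-2.66), Fas (-2.43), Ccng1 (-1.39) and Plk2 (-1.11) among the lower.

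Genes of oxidative stress and xenobiotic metabolism had 12 of 25 higher and 5 lower (median 0.12, adjusted p 0.493), with Sod2 (1.46) and Sult1a1 (1.41) higher and Cyp1b1 and Nqo1 (-1.80) lower. Hypoxia and glycolysis genes had 8 of 19 higher and 4 lower (median 0.28, adjusted p 0.579), with Aldoc (1.01) and Tpi1 (0.69) higher and Eno1 (-1.27) and Hk1 (-0.96) lower. Endothelial markers moved little (median 0.02, adjusted p 0.478), with Ednrb (1.54), Kdr (0.52) and Sele (0.24) higher and Ramp2 (-0.33) lower. Cell cycle genes had 1 of 8 called higher, Aurkb (0.18), and 1 lower, Plk1 (-0.59), with a median of 0.00 (adjusted p 0.780). Aurkb lost its call without BCA 1, 2 or 4 or o-NT 2 or 3, and Plk1 without any 1 tumour other than o-NT 2.

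Of the lists of reproductive tissue, Leydig and Sertoli cell markers had Gata4 (0.44) and Cyp11a1 (0.25) higher beside Rhox5 and Cyp17a1 lower (-0.14), with a median of 0.05 (adjusted p 0.377). Epididymis and secretory epithelium markers had Epcam (1.65), Adam7 (0.32) and Aqp5 (0.13) higher and Spink1 lower (-0.27), with a median of 0.05 (adjusted p 0.377). Testis germ cell markers barely moved (median -0.02, adjusted p 0.492), with Acr (-0.15) and Akap4 (-0.07) lower. Akap4 lost its call without any 1 tumour other than BCA 1 and o-NT 1. For the stress MAPK and oxidative stress lists the mean was below 0 while the median and the camera direction were above it, and for the cell cycle list the median alone was above 0.

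**Figure D2:**
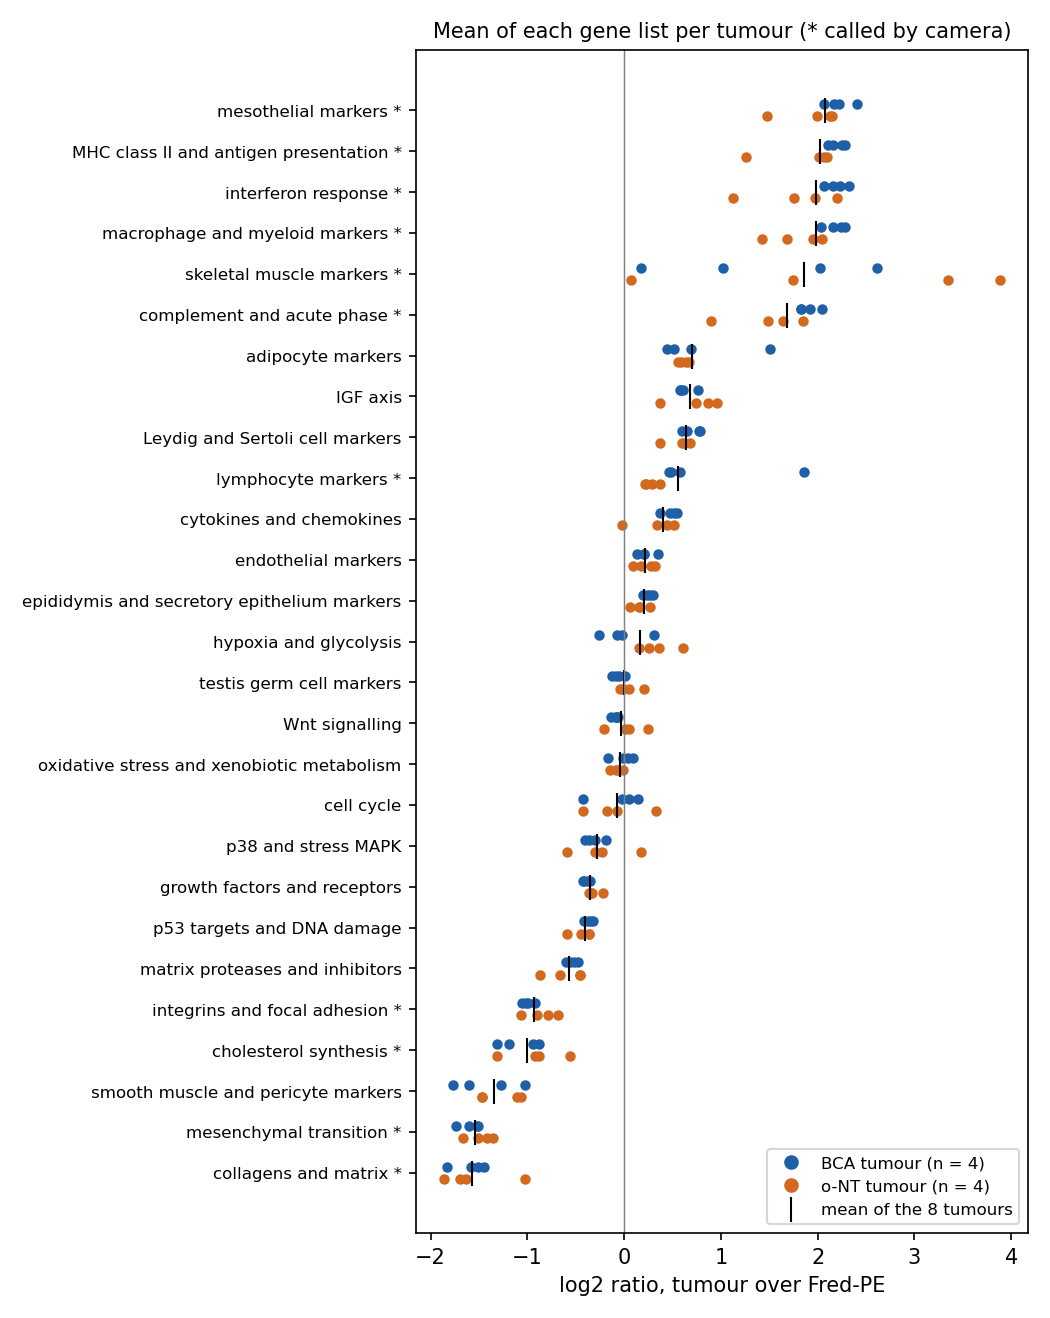
Mean log2 ratio over Fred-PE of the measured genes of each list, per tumour (BCA blue, o-NT orange, 4 each; bars mark the mean of the 8 tumours, stars the 11 lists called by camera). The muscle list spreads from 0.07 to 3.88, and BCA 4 stands alone in the lymphocyte list at 1.86.

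Among the genes fixed by name, Mapk14 was higher by 0.22 ± 0.02 in 8 of 8 tumours, and Vegfa fell by 1.39 and Nqo1 by 1.80 in 8 of 8. Igf2 rose by 1.5 ± 0.35 in 7 of 8 tumours, and Cdkn2a fell by 0.14 in 8 of 8. Fibronectin (Fn1) fell by 1.05, and its reference signal was saturated on every array, so Fn1 was at least 2.07-fold lower. Calb2 (0.01), Top2a (0.02) and Hmox1 (0.00) were not called, with adjusted p of 0.881, 0.716 and 0.992. Igf1, Egfr, Met, Ctnnb1, Nf2, Mki67, Ptprc and Cd68 were not measured under these names. The tumours differ from Fred-PE in being tissue, not cultured cells, and the design holds no normal mesothelium.

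Taken by chemical, most probes called in the o-NT tumours were called in the BCA tumours too. Msln rose by 4.85 ± 0.09 in the BCA tumours (SD, n = 4) and by 4.30 ± 0.54 in the o-NT tumours (SD, n = 4), and Ccn2 fell by 6.53 in the former and fell by 5.88 in the latter. The BCA tumours had 7841 probes called, 3941 higher and 3900 lower, and the o-NT tumours 5769, 2654 higher and 3115 lower. Of the probes higher in the o-NT tumours 2316 were higher in the BCA tumours too, against 533 for independent lists, and of the lower ones 2796, against 619. Independent lists leave out the shared reference, which in the 20 simulations of unchanged tumours alone gave overlaps of 836 higher and 831 lower, from 1485 and 1476 calls in the o-NT group. A single probe, of Csnk1a1, was called lower in the BCA and higher in the o-NT tumours.

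Across the 19628 probes, the mean log2 ratios of the BCA and o-NT groups correlated at r = 0.947 (Spearman's rho 0.867), with a slope of 0.84 of o-NT on BCA. Both groups were divided by the same reference RNA, which makes such ratios correlate without any change in the tumours. In 20 simulations of unchanged groups sharing 1 reference sample, the mean r was 0.802 and the mean covariance 0.0545, against an observed covariance of 0.374. The share of probes with the same sign was 82.4%, against 79.5% in the simulations. The share of the correlation that comes from the reference cannot be separated here.

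**Figure D3:**
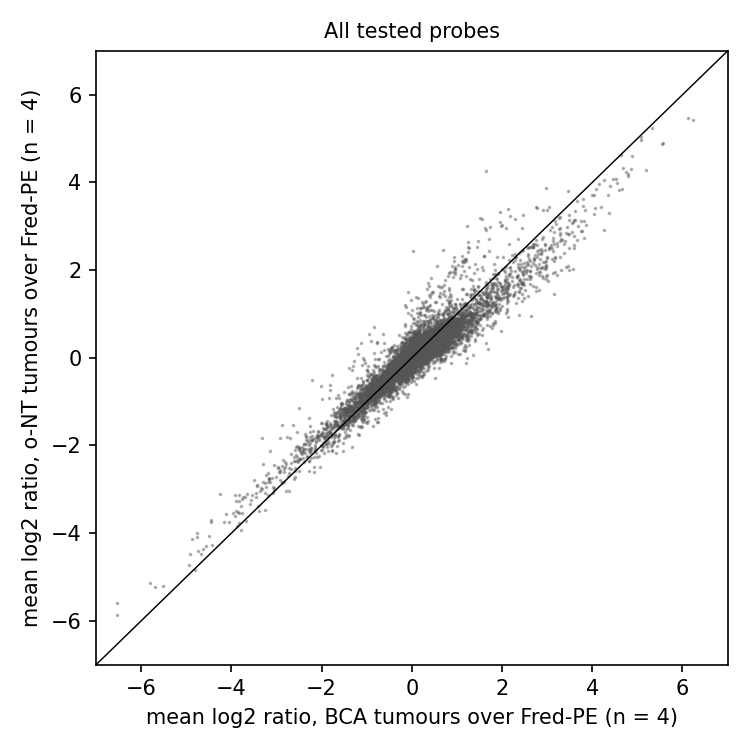
Mean log2 ratio over Fred-PE in the o-NT tumours against the BCA tumours, 4 tumours each, with 1 point per tested probe and the line of equality. The points follow the line at r = 0.947, with somewhat smaller ratios in the o-NT tumours.

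The direct comparison asks whether the chemicals left different expression in the tumours. The amino acid transporter Slc7a9 was higher in the BCA tumours, at 3.57 ± 0.23 over the reference against 2.03 ± 0.48 in the o-NT tumours (SD, n = 4 each). The peptidase Dpp4 was at 2.11 ± 0.13 against 1.26 ± 0.31, and the hydrolase Ggh at 0.64 ± 0.14 against -0.05 ± 0.15 (3 o-NT tumours, without a value in o-NT 3). Casein kinase Csnk1a1 was below the reference in all 4 BCA tumours (mean -0.22) and above it in all 4 o-NT tumours (mean 0.37). None of these genes passed correction. With all 16 arrays, a dye term and the tumour as a random block, Slc7a9 (adjusted p 0.00232), Dpp4 (0.0299), Ubqln1 (0.0449) and the other probe of Ggh (0.0299) were called. That fit sets 1 correlation, 0.448, between a tumour's arrays for all probes, so the 2 arrays count partly as separate replicates.

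No probe was called by limma between BCA and o-NT tumours. At an unadjusted p under 0.05 there were 1617 of 19628 probes, or 8.24%, and the lowest adjusted p was 0.0908. An exact permutation test per probe gave 980 of 18851 probes with a value in all 8 tumours at an exact p under 0.05. This was 5.20%, against 2.86% by chance. The smallest p that 4 against 4 tumours can give is 0.0286, so the lack of calls by that test after adjustment says nothing further. Of the genes, 6.21% had no overlap between the groups, against 2.86% by chance. The 10 genes with the smallest p included Ppp1r14c (-0.42), Lhx5 (-0.30), Pln (-0.29), Slc29a1 (-0.34), Ubqln1 (-0.41) and Ddx25 (0.20), as BCA minus o-NT, and all 10 had adjusted p from 0.293 to 0.424. Lhx5 was well above background in the tumour channel on only 4 of 16 arrays. None of the 12 measured genes fixed by name was called, with the lowest adjusted p at 0.497, for Vegfa.

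An unnamed probe, described in the files as similar to the mouse B lymphocyte chemoattractant, was singled out after its values were seen. It was at 1.96 to 3.16 log2 units over the reference in the 4 o-NT tumours and at -0.03 to 0.10 in the 4 BCA tumours, a difference of -2.41 ± 0.24 (SE) with an adjusted p of 0.113. It was called under 6 of the alternatives, among them both sets of deposited ratios.

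Gene lists gave 6 calls by camera between the chemicals. Hypoxia and glycolysis genes were lower in the BCA tumours, with a median difference of -0.36 (adjusted p 2.90e-05, adjusted p = 0.391 with an estimated correlation and 0.233 by fry), from a list mean of -0.01 ± 0.24 in BCA against 0.35 ± 0.19 in o-NT tumours (SD, n = 4 each). Lymphocyte markers were higher in BCA tumours by 0.58 (adjusted p 0.0137), interferon response genes by 0.49 (0.00882), macrophage and myeloid markers by 0.42 (0.00980) and MHC class II and antigen presentation genes by 0.41 (0.0137). Integrins and focal adhesion genes were lower in BCA tumours (-0.15, adjusted p 0.0205). With an estimated correlation each of these 5 lists also had an adjusted p = 0.391. The largest differences among hypoxia and glycolysis genes were in Tpi1 (-0.91), Aldoa (-0.88), Bnip3 (-0.85) and Ldha (-0.77), and none passed correction. Skeletal muscle genes, which varied with 3.88 in o-NT 1 and 0.07 in o-NT 2, were not called between the chemicals (median -0.91, adjusted p 0.172), though without o-NT 2 they were (-1.77, adjusted p 0.00485), and the median ranged from -1.77 to -0.28 with 1 tumour left out.

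These list differences rest on few tumours. No member of the 6 lists was called over all probes, and when adjusted over the list alone 3 macrophage and 2 interferon genes were called higher and 1 integrin gene lower. By fry none of the 27 lists passed (lowest adjusted p 0.0867). Without o-NT 1 the interferon difference fell to 0.25 and lost its call (adjusted p 0.0532), the macrophage difference fell to 0.21 and that of MHC class II to 0.20. Without BCA 4 the lymphocyte difference fell to 0.11 and that of hypoxia and glycolysis to -0.23, and without o-NT 3 the latter was -0.21 and the lymphocyte list lost its call (adjusted p 0.0694). The MHC class II list lost its call without BCA 3, and the integrin list without BCA 3, o-NT 2 or o-NT 3.

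Cholesterol synthesis genes, lower in BCA tumours (-0.17, adjusted p 0.0830), passed without BCA 1, BCA 2 or o-NT 1, and with the day as a fixed block (-0.54, adjusted p 4.30e-07), and complement genes, higher by 0.10 (adjusted p 0.0779), passed without BCA 2, o-NT 2 or o-NT 3. Mesothelial markers (0.29, adjusted p 0.0893) passed without o-NT 3, muscle markers without o-NT 2, and oxidative stress genes (0.00, adjusted p 0.165) without BCA 1. The other 16 lists had adjusted p from 0.155 to 0.997. Extraction day 2 was the single day with both chemicals, and held the tumours at the higher doses. Within it, 2 BCA tumours against 2 o-NT tumours gave 0 called probes and 1265 at an unadjusted p under 0.05. The mean of the hypoxia and glycolysis list differed by -0.65 within that day, lymphocyte markers by 0.96, macrophage markers by 0.38, interferon genes by 0.33, MHC class II genes by 0.18, integrins by -0.19, cholesterol synthesis genes by -0.52 and skeletal muscle markers by -1.45.

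**Figure D4:**
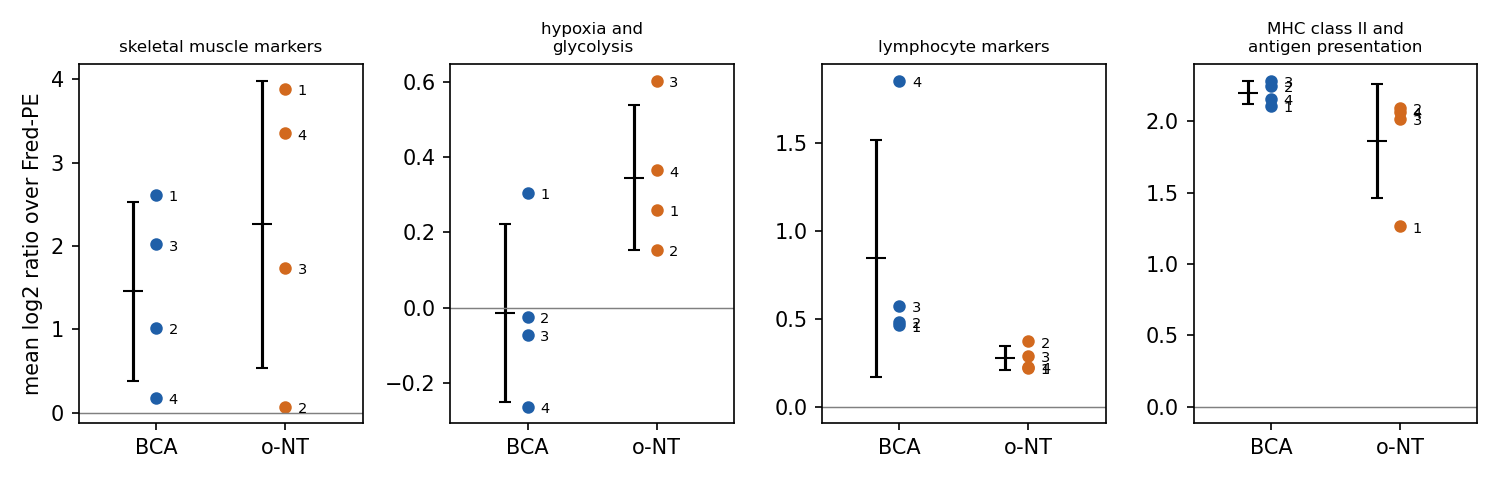
Mean log2 ratio over Fred-PE of 4 gene lists in each BCA and o-NT tumour, with the replicate number beside each point and the group mean and SD as bars. BCA 4 stands apart for lymphocyte markers and o-NT 1 for MHC class II, while muscle markers spread widely within both groups.

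The last comparisons ask whether dose left a trace within a chemical. Between o-NT tumours at 2000 ppm and at 1250 ppm no probe was called by limma, with 1042 at an unadjusted p under 0.05 and a lowest adjusted p of 0.235. Without o-NT 1 there were 14 calls and without o-NT 2 there were 374, each with a single tumour at 1250 ppm that was assumed to vary like the others. The 1250 ppm tumours were extracted on day 1 and the 2000 ppm tumours on day 2, so dose and day cannot be told apart. Skeletal muscle genes differed as much within 1250 ppm (3.88 and 0.07) as anywhere among the 8 tumours.

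Over BCA doses from 250 to 1000 mg/l no probe had a called slope by limma, with 799 at an unadjusted p under 0.05 and a lowest adjusted p of 0.9998. Lymphocyte markers were at 1.86 in the tumour at 1000 mg/l against 0.46 to 0.57 in the 3 others, but a single tumour stood at that dose. Without BCA 3 there were 20 calls. Both 250 mg/l tumours were extracted on another day than those at 500 and 1000 mg/l, and with the day as a block 14 probes were called, from 1 tumour at each of the higher doses.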

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

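Tests chosen only after the result was seen were those of chemical and extraction day for the muscle genes, both tests of the immune lists, the muscle list mean as a covariate, and the use of the day block and of equal spread, both planned as alternatives, to judge the lists called between the chemicals.

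In 297 groups of 4 tumours (each gene reported, list mean and measure of agreement in each chemical), 21 had a tumour far from the others, where chance gives about 14.9. The gap to the nearest other tumour, as a share of the group's range, is given for each. Tumour o-NT 1 was lowest among o-NT tumours for Rhox5 (2.40 against 4.66 to 5.08, share 0.843), Hk1 (0.862), Actn4 (0.872), Psmb8 (0.878), Wnt4 (0.833) and the MHC class II and antigen presentation list (1.26 against 2.01 to 2.09, share 0.905). Tumour o-NT 2 was highest for Ccn3 (-3.38 against -5.84 to -5.61, share 0.906) and Spp1 (0.885) and lowest for the muscle gene Myl11 (0.28 against 4.13 to 4.63, share 0.885). Tumour o-NT 3 was highest for Bdnf (0.848) and Gadd45a (0.918), and o-NT 4 lowest for Itgb5 (0.948).

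Among BCA tumours, BCA 4 was highest for the lymphocyte list (1.86 against 0.46 to 0.57, share 0.920), Il2rb (2.69 against 0.62 to 0.69, share 0.963), Nkg7 (0.868) and Ddah1 (0.869). BCA 2 was highest for Cnn1 (0.913) and Adam7 (0.846) and lowest for Adamts1 (0.953). BCA 1 was highest for the IGF axis list (0.832), and BCA 3 had the widest spread of log2 ratios (0.704 against 0.685 to 0.688, share 0.841).

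The change from the reference differed between BCA and o-NT tumours for 6 gene lists by the camera test of the difference itself. None of them passed with an estimated correlation (adjusted p = 0.391 for each), and no list passed by fry (lowest adjusted p 0.0867). The median differences, BCA minus o-NT, were -0.36 for hypoxia and glycolysis, 0.49 for interferon response, 0.42 for macrophage and myeloid markers, 0.41 for MHC class II and antigen presentation, 0.58 for lymphocyte markers and -0.15 for integrins and focal adhesion.

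Skeletal muscle genes were far above the reference in some tumours and near it in others. The chemical does not explain the spread by itself, since the list mean ranged over 2.43 log2 units within BCA tumours and 3.81 within o-NT tumours, against a difference of -0.81 between the group means (exact permutation p 0.457, two-sided). The day does not either, since the 4 tumours of day 2 ranged over 3.17. Muscle tissue taken along with the tumour is a candidate explanation that stays open. In a second list of 57 muscle genes, none on the first list and written before it was looked at, 27 of 30 measured genes were higher in the 4 tumours with the highest list means, with a median of 0.49, just short of the 0.5 set beforehand. The highest median of 1000 random gene sets of that size was 0.04.

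The MHC class II, interferon, macrophage, complement and lymphocyte lists had means above the reference in all 8 tumours, while the cytokine and chemokine list, which was not called, was at -0.02 in o-NT 1. A loss of mesothelial cells that raises every other cell type alike was predicted to give the lists of other cell types like means. Macrophage markers averaged 2.01 and endothelial markers 0.22 (exact permutation p over genes 0.0103). Lymphocyte markers averaged 0.56, adipocyte markers 0.71 and smooth muscle markers -1.44, and were not in that test. The test cannot decide the question, since genes are not replicates and a ratio also depends on the gene's level in Fred-PE. Mesothelial markers rose too. Immune cells within the tumour tissue remain a candidate explanation that no test here decides. That 17 of 26 macrophage and lymphocyte genes that no other list holds were called higher and 0 lower restates the pattern and supports no cause. Expression of these genes by the tumour cells themselves was not tested.

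For the 6 lists called between the chemicals, the muscle share of the tumours is argued against as the whole cause, because 6 of 6 remained called in their direction with the muscle list mean as a covariate. A part due to muscle stays open, since the medians went from 0.49 to 0.33 for interferon, 0.42 to 0.31 for macrophage and 0.41 to 0.33 for MHC class II genes, with adjusted p up to 0.0487, for the lymphocyte list. The extraction day and larger log ratios throughout on the BCA arrays are argued against as the whole cause for hypoxia and glycolysis. Its median went from -0.36 to -0.59 with the day as a block (adjusted p 8.91e-10 by camera on moderated t values). Larger log ratios would put a list further from 0, but the mean of this list was -0.01 in BCA and 0.35 in o-NT tumours. Making the spread of the ratios equal between arrays could therefore hardly remove the difference. The median of -0.56 found with it (camera adjusted p 3.15e-06) adds no support. The day block compares 2 tumours per chemical, those of day 2. These were also the tumours at the higher doses, 500 and 1000 mg/l of BCA and 2000 ppm of o-NT. A shift with the day block therefore cannot be told apart from a shift with dose, for any of the lists. Both p-values take genes as nearly independent, and with an estimated correlation the list in the reported fit had an adjusted p = 0.391. The day is argued against as the whole cause for the lymphocyte list too, at a median of 0.53 with the day as a block (0.58 without) and an adjusted p of 0.000233. The same limits hold, and BCA 4 carries most of that difference. The day stays open for the 4 other lists. With it as a fixed block, which leaves 2 tumours per chemical to compare, 0 of the 4 were called. The medians went from 0.49 to 0.35 for interferon, 0.42 to 0.21 for macrophage, 0.41 to 0.23 for MHC class II and -0.15 to -0.11 for integrin genes. With the day as a random block all 6 lists stayed called in their direction, where the list test changed too. The correlation within a day was estimated there at -0.115. The calls thus depend on how the day is modelled. Differences of the list means, from all tumours to day 2 alone, went from 0.43 to 0.33 for interferon and 0.34 to 0.18 for MHC class II. For macrophage genes they went from 0.40 to 0.38 and for integrin genes from -0.13 to -0.19. Larger log ratios stay open for the 5 lists other than hypoxia and glycolysis. With equal spread 0 of the 5 were called, and the medians went to 0.08 for macrophage, -0.02 for interferon, -0.027 for MHC class II and 0.01 for integrin genes. The lymphocyte list kept a median of 0.37 of its 0.58 and missed the threshold (adjusted p 0.0766), so its lost call says little for larger log ratios. Equal spread also removes a true difference in overall size, so the wider ratios may be either technical or an effect of the chemical. They were not confined to BCA tumours, as the SD of the log2 ratios was 0.685 to 0.704 in these, 0.701 in o-NT 1 and 0.604 to 0.642 in the other o-NT tumours, and o-NT 1 had the lowest interferon and MHC class II means.

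Chance cannot be excluded for these lists as a set. The real split called 6 lists. Of the 35 splits of the 8 tumours into 4 and 4, 6 splits, the real one included, called at least as many. The highest other called 8, with BCA 1 and o-NT 2, 3 and 4 on 1 side. For the hypoxia and glycolysis list alone, 3 of the 35 splits, the real one included, gave an adjusted p as low as the real one. For called probes the splits decide nothing, since the real split called 0, which all 35 reach by definition, with 1 in the highest other. For probes at an unadjusted p under 0.05 the real split was the highest of the 35, with 1617 against 1578 in the next (1 of 35 splits). This is the smallest share the design can give. The margin is narrow and the splits differ in how they divide the days, so chance cannot be excluded for that count either. The count was 955 with the day as a fixed block, 1797 with the day as a random block and 1071 with equal spread. A fixed block that leaves 2 tumours per chemical can lower the count by itself, and equal spread also removes a true difference in overall size. The count therefore cannot separate an effect of the chemicals from the day or from larger log ratios. The split with the next highest count had BCA 1 with o-NT 1, 3 and 4 on 1 side.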

How the results depend on the processing

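The counts of probes called against the reference stayed within 1.5 times of the reported ones under all 23 alternatives run for them. They ranged from 8342 to 10828 for all tumours, from 6055 to 8992 for BCA and from 4326 to 6858 for o-NT tumours. The correlation of BCA with o-NT changes ranged from 0.914 to 0.965. No normalization moved the median log2 ratio of all probes by more than 0.03.

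The count of 0 between BCA and o-NT tumours became 1 with the scanner's deposited ratios, with the series table, with a normexp offset of 0, with arrays with the tumour in Cy5 alone and with an intensity trend and robust estimation. It became 51 with all 16 arrays, a dye term and the tumour as a random block. Leaving out 1 tumour gave 0 to 1. With the same 16-array fit the o-NT dose comparison (o-NT 2000 minus 1250 ppm) called 143 probes and the BCA log2 dose slope 87. Leaving out 1 tumour gave 0 to 374 and 0 to 20 for these. The BCA slope called 14 with the day as a fixed block. The o-NT dose comparison could not be fitted with the day, and the random day block was run only for the group means. The cause of these changes was not tested.

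The 11 lists called against the reference became 0 with an estimated inter-gene correlation and 22 by fry, which tests another question. The 6 called between the chemicals became 1 with scale normalization between arrays, 3 with the day as a fixed block (2 of the 6, hypoxia and glycolysis and lymphocyte markers, with cholesterol synthesis newly called, adjusted p 4.30e-07), 0 with an estimated correlation and 0 by fry. With the tumour in Cy5 alone, interferon (camera adjusted p 0.0877) and integrin genes (0.119) lost their call. Mesenchymal transition and testis germ cell genes gained one there (0.0438 each). With a normexp offset of 0 the integrin list lost its call (camera adjusted p 0.0571). With the day as a random block the same 6 lists stayed called, where the list test changed too.

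Of the 121 genes taken by the naming rule against the reference, 2713 of 2765 values kept their direction and side of the threshold, 49 lost a call, 2 gained one and 1 reversed. That was Top2a, at -0.12 with the tumour in Cy3 alone. These counts do not cover size, which without background correction shrank, for example, from 1.88 to 0.88 for Fabp4 and from 0.85 to 0.51 for Nkg7. Apart from leaving out tumours, Ccng1, Cdkn2a, Sele, Cyp17a1 and Plk1 lost their call with the tumour in Cy3 alone, Axin1, Scd2, Aurkb and Akap4 with the tumour in Cy5 alone, and Fabp4, Nkg7, Il2rb and Akap4 without background correction. Aurkb and Akap4 also lost it with median centring and in the 16-array fit, and Aurkb with outlier spots kept. For the 27 lists, 653 of 699 values against the reference and 707 of 753 between the chemicals were the same, and 1 reversed. That was MHC class II and antigen presentation, at -0.027 between the chemicals with scale normalization. In the dimmest 20% of probes a tumour's 2 arrays correlated at 0.398 to 0.713, against 0.932 to 0.972 in the brightest 20%. The reason for the lower values was not tested.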
